A study of Drosophila melanogaster with 6 samples.

How the data were processed

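Total RNA from 1st instar larvae was labelled with biotin and hybridised to Affymetrix arrays, per the labels. The labels give 3 biological replicates of 200 larvae for each of 2 genotypes, and a collection time of about 48 after egg laying without a unit. The deposited values are log2 expression values per probe set made with RMA, per the submitters' processing notes. The version of RMA is not given in the sources used here, and the log2 scale was taken from the range of the values. Scanner files were not used here. RMA puts all arrays on nearly 1 distribution, so a change shared by most genes is not visible in these values.

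Of 18952 probe sets, 183 controls were left out. In the platform's probe table of 2016, 13647 probe sets name 1 gene, 402 name several and 4720 are unlisted. Probe sets with exactly 1 gene were used, and for each gene the probe set with the highest mean over the 6 arrays was kept, which gave 11983 genes. Of these, 11894 (99.3%) matched the NCBI table of Release 6 of the Drosophila genome, used for names, arms and gene order only. For 1094 genes there was more than 1 probe set.

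Mutant and control were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes and calls at an adjusted p under 0.05. Gene lists were tested with camera at a preset correlation of 0.01 and adjusted over the lists with at least 5 measured members. Arms and the 20 genes on each side of Kdm4A were tested with Fisher's exact test, two-sided, and arms with camera too. The groups, tests, gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule named Kdm4A, Kdm4B, w and y, and up to 12 genes with the largest increases and 12 with the largest decreases among called genes whose groups did not overlap. It also allowed naming up to 4 members with the smallest p in each list, arm or neighbour set described, and any homeotic gene. With fewer than 5 called in a direction it would have taken the 5 smallest p.

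The replicate numbers were checked for pairing. Over the genes tested, deviations from the group mean correlated between same-numbered arrays at 0.684, 0.151 and 0.756 for numbers 1, 2 and 3, so the numbers were taken to pair the arrays, and values with the replicate number as a block are given where they change a call or count. The pairing rests on the titles' numbers and on these correlations, which are not 3 separate supports. Deviations within a group sum to 0, so the values for numbers 1 and 3 largely hold 1 gradient. Mutant 1 correlated with control 3 at -0.687, and mutant 3 with control 1 at -0.695. Mutant 2 correlated more with control 1 (0.354) than with control 2. No identical arrays were found.

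Alternatives were quantile normalization, median centring, a filter keeping the upper 60% of genes by mean, all probe sets, the mean of a gene's probe sets, a trended robust prior, array weights (statmod 1.5.0), the replicate block, other set tests, other numbers of neighbours, and leaving out each array. The fits were tested on simulated data made from the levels, spreads and pair effects of the 11983 genes, with 200 genes changed, for the comparison of mutant and control. Without the block 68.7% of 2-fold and 92.8% of 4-fold changes were recovered, with 0.7 false calls on average. With the block 69.8% and 93.1% were recovered, with 4.6 false calls. The simulation drew noise independently for each gene and gave both groups the same pair effects. It also changed more genes than either fit called in the data. These rates may therefore not hold for the data. Plots were drawn with matplotlib 3.10.9.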

Results

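Gene expression was measured on Affymetrix arrays in whole 1st instar larvae of Drosophila melanogaster. The mutant larvae carried an insertion allele of Kdm4A over a deletion of the gene. The control larvae carried a pair of alleles from which insertions had been excised precisely. The labels give the insertion of the mutant as KG04636 and 1 of the excised insertions as KG06436, and whether these are the same insertion is not settled here. Each group had 3 arrays, labelled as biological replicates, and each array held RNA from 200 larvae raised at 25 °C. The arrays reported 18952 probe sets, and their median values lay between 5.29 and 5.37 on the log2 scale. The comparison asked which genes depend on Kdm4A, which encodes a histone lysine demethylase of the JmjC family. The number of arrays limits the precision of every value below.

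Kdm4A itself was lower in the mutant, by 3.79-fold in the array values. Its log2 value was 3.38 ± 0.08 (SD, n = 3) in the mutant and 5.30 ± 0.14 (SD, n = 3) in the control, a difference of -1.92 with an SE of 0.10 and a limma adjusted p of 0.00174. In the mutant arrays Kdm4A lay between percentiles 5.53 and 8.58 of all genes, and in the control arrays between percentiles 33.7 and 35.9. Its mutant values lay below the lower quartiles of the arrays, 3.69 to 3.79, and were not tested against background, so the fold can understate the decrease. One probe set named the gene, and whether it lies inside the deleted part is not given in the sources used here. Without both arrays numbered 1, which leaves 2 against 2, the adjusted p of Kdm4A was 0.077. The body colour gene y, which some insertions carry as a marker, differed by 0.03 with an SE of 0.55 (adjusted p = 0.998, n = 3 per group). Kdm4B and w were not analysed here.

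Among 11983 genes, 8 rose and 11 fell in the mutant at a limma adjusted p under 0.05. The largest increase among these 19 genes was that of Cpr67Fa2, which encodes a structural protein of the cuticle and rose 13.7-fold (log2 difference 3.78, SE 0.35, adjusted p = 0.0214, n = 3 per group). CG32687 rose by 2.88 (SE 0.11), CG34278 by 2.61 (SE 0.09), CG40298 by 2.57 (SE 0.21) and nkt by 2.32 (SE 0.23). Smaller increases were found for CG17283, with a log2 difference of 1.22, for the glutamate receptor gene Ekar, with 0.99, and for Ppcs, an enzyme gene of coenzyme A synthesis, with 0.95. The largest decrease among them was that of eIF4E3, which encodes a cap-binding translation initiation factor and fell 6.65-fold (log2 difference -2.73, SE 0.15, adjusted p = 0.00174, n = 3 per group). CG32572 fell by 2.65 (SE 0.22), CG4783 fell by 2.46 (SE 0.23) and CG14419 fell by 2.18 (SE 0.25). Ugt35B1, a UDP-glycosyltransferase gene of detoxification, fell by 2.21 (SE 0.12). CG15369, CREG, lute and Sclp had log2 differences of -1.74, -1.58, -1.15 and -1.05. Cbl, which encodes a ubiquitin ligase of receptor tyrosine kinases, fell by 0.97.

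In each of these 19 genes all 3 mutant values lay on the same side of all 3 control values, and 16 differed at least 2-fold, 6 upwards and 10 downwards. The second probe sets of Cbl, lute and Ppcs had log2 differences of 0.14, -0.12 and 0.47 and did not pass. At an unadjusted p under 0.05 there were 632 genes, and 1339 with the replicate number as a block, where chance gives 599. With this block, limma called 98 genes, 35 higher and 63 lower, of which 62 differed at least 2-fold, and all 19 genes were among the 98. Some of the added genes had overlapping groups, such as ng3 (log2 difference 1.45) and Mtk (-1.31), named after their values were seen. With genotype in the fit, both also differed between array numbers 3 and 1, by -2.51 and -2.34 (limma adjusted p = 0.011 and 0.0113). The block, which gave the SE and adjusted p printed here, added CG14418 (-3.03, SE 0.18, adjusted p = 0.00717) and CG10943 (-2.78, SE 0.21, adjusted p = 0.014), both lower by more than eIF4E3, and CG34330 (3.31, SE 0.34, adjusted p = 0.0272), named after their values were seen. CG32687, CG34278, eIF4E3, Kdm4A and Ugt35B1 passed whichever array was left out. The other 14 genes lost the call in at least 1 case, and 5 genes remained without mutant replicate 1, without mutant replicate 2 or without control replicate 2. Without both arrays numbered 1, limma called 0 genes without the block, with 441 at an unadjusted p under 0.05, and 89 genes with it. With the block this leaves 1 residual degree of freedom per gene, so the 89 calls lean on the spread that limma pools over genes.

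**Figure D1:**
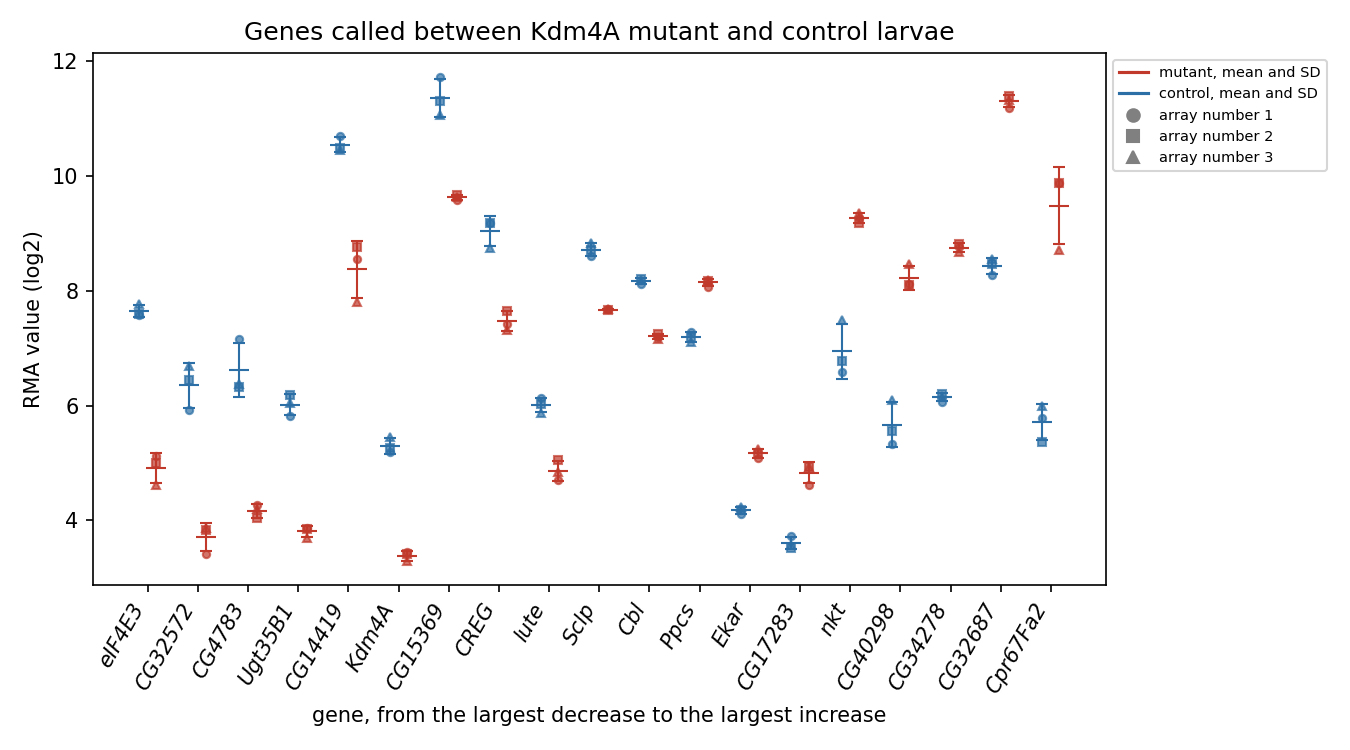
RMA values (log2, vertical axis) of the 19 called genes, ordered from the largest decrease to the largest increase; bars are the mean and SD of 3 arrays and symbols are single arrays. Cpr67Fa2 had a mean of 9.49 in the mutant and 5.71 in the control, and eIF4E3 had 4.92 and 7.65.

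Of 33 gene lists tested with camera at the preset correlation, 3 passed, and 0 passed with an estimated correlation (adjusted p = 0.938 for each of the 3). Cuticle protein genes had a mean log2 difference of 0.27, with 80 of 106 measured members higher in the mutant (camera adjusted p = 2.84e-05, and adjusted p = 0.938 with an estimated correlation). Of these, Cpr67Fa2 alone passed over all genes, and 3 passed adjusted over the list alone, the others being Cpr72Ec (0.60, SE 0.08) and Cpr97Eb (1.24, SE 0.23). Cpr76Bb had a difference of 1.17 (SE 0.31) and did not pass. With the replicate block 5 members higher and 2 lower passed adjusted over the list alone. The list mean was lower in the mutant in pair 1, by -0.19, and higher in pairs 2 and 3, by 0.54 and 0.46. Without control replicate 3 the mean difference was -0.06 (adjusted p = 0.757), and without mutant replicate 1 it was 0.08 (adjusted p = 0.209). These fits had no block and left the groups unequal in replicate numbers.

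Muscle sarcomere genes, which encode contractile proteins, had a mean log2 difference of 0.16, with 24 of 26 members higher in the mutant (camera adjusted p = 9.16e-04, and adjusted p = 0.938 with an estimated correlation). By limma 0 members passed over all genes, with 4 at an unadjusted p under 0.05. Adjusted over the list alone, 1 passed, Mlp60A, with a difference of 0.59 (SE 0.11), and with the replicate block TpnC41C passed too. Mlp84B differed by 0.51 (SE 0.14), TpnC41C by 0.59 (SE 0.18) and Act79B by 0.21 (SE 0.08). The difference of the list mean was 0.46 in pair 1, 0.07 in pair 2 and -0.06 in pair 3. Without control replicate 1 the mean difference was 0.01 (adjusted p = 0.912), without both arrays numbered 1 it was 0.01 (adjusted p = 0.969), and with array weights the adjusted p was 0.0546.

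Glutathione S-transferase and UDP-glycosyltransferase genes, which encode conjugating enzymes of detoxification, had a mean log2 difference of -0.12, with 45 of 70 members lower in the mutant (camera adjusted p = 0.0485, and adjusted p = 0.938 with an estimated correlation). Ugt35B1 alone passed, over all genes and adjusted over the list alone. GstE5 differed by -0.53 (SE 0.12), GstD3 by -0.95 (SE 0.25) and GstD9 by 0.70 (SE 0.18). With the replicate block GstD3 passed as well (adjusted p = 0.0232), 3 members were called lower over all genes, and adjusted over the list alone 8 were lower, GstE5 among them, and 1 was higher. With the replicate block the adjusted p of the list was 0.0564. The adjusted p also missed the threshold with the dim probe sets left out (0.0636), on ranks (0.217), without both arrays numbered 1 (0.678), and without mutant replicate 1 (0.611), mutant replicate 2 (0.055), control replicate 1 (0.103) or control replicate 2 (0.0871).

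**Figure D2:**
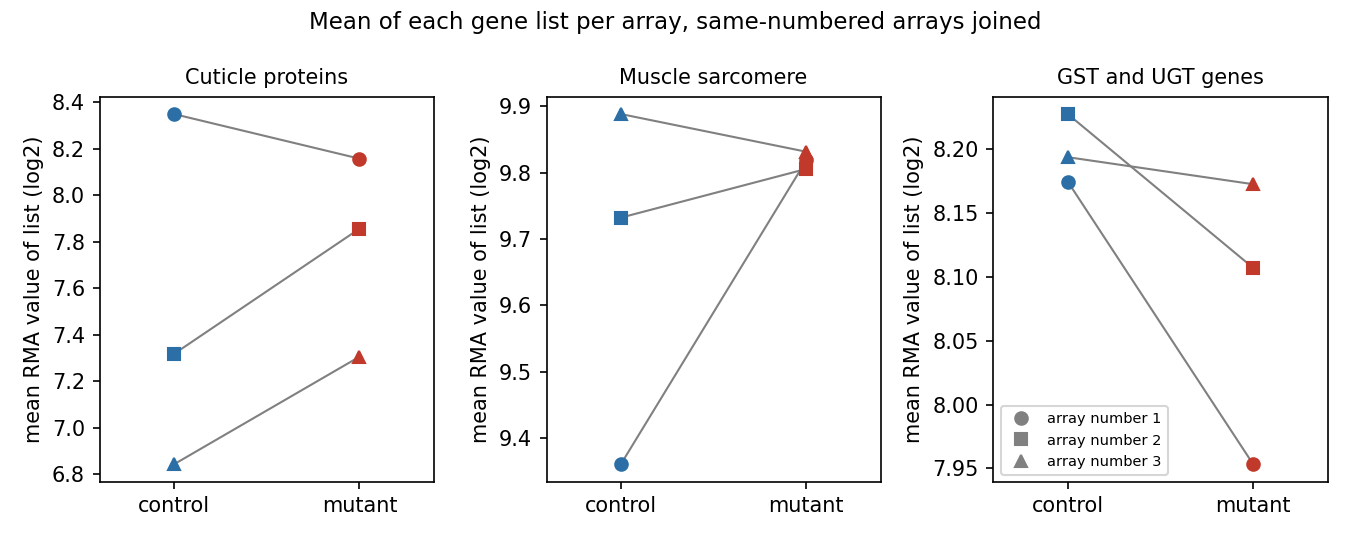
Mean RMA value (log2, vertical axis) of the cuticle, muscle sarcomere and glutathione S-transferase and UDP-glycosyltransferase lists in each array, with lines joining arrays of the same number. The cuticle mean was 8.35 in control 1 and 8.16 in mutant 1, against 6.84 in control 3 and 7.30 in mutant 3.

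The remaining 30 lists had camera adjusted p values from 0.315 to 0.909. Ecdysone synthesis and response genes, which act in molting, had a mean difference of -0.18, with 19 of 31 members lower (adjusted p = 0.315). Adjusted over the list alone, 0 members passed without the block, and with it 6 were lower and 2 higher, among them ImpE3 (-0.60, SE 0.19), Blimp-1 (-0.46, SE 0.16) and spok (0.59, SE 0.16). Cytochrome P450 genes had a mean difference of 0.06, with 44 of 80 members higher (adjusted p = 0.315). Cyp12a5, with a difference of 1.55 (SE 0.23), passed adjusted over the list alone (adjusted p = 0.0327) but not with the replicate block (adjusted p = 0.0514). Genes of heterochromatin and of H3K9 or H3K36 methylation had a mean difference of -0.05 over 21 members (adjusted p = 0.507), and HP6, with the smallest p, differed by -0.20 (SE 0.10). Genes resident in pericentric heterochromatin had a median difference of -0.03 and a mean of 0.02 over 25 members, where camera gave the direction as up (adjusted p = 0.862). Scp1 in this list had a difference of 0.82 (SE 0.13), with a limma adjusted p of 0.111 over all genes, 0.0121 adjusted over the list alone, and 0.0354 over all genes with the replicate block. Homeotic genes had a mean difference of 0.01 over 6 members, where camera gave the direction as down (adjusted p = 0.862), from pb with -0.14 (SE 0.10) to Antp with 0.22 (SE 0.33). Y-linked genes had a mean difference of 0.01 over 7 members (adjusted p = 0.862), and kl-3, with the smallest p, differed by -0.15 (SE 0.11). Of the 12 JmjC demethylase genes measured, Kdm4A alone passed, and the list had a median difference of 0.01 and a mean of -0.12 (adjusted p = 0.909).

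The 3′ to 5′ gap of the control probe sets, a sign of RNA quality, was larger in both arrays numbered 1 than in the other arrays. For actin it was 2.37 in arrays numbered 1, 1.68 in arrays numbered 2 and 1.62 in arrays numbered 3. Between the genotypes the actin gap was 1.85 ± 0.47 (SD, n = 3) in the mutant and 1.93 ± 0.37 (SD, n = 3) in the control.

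Genes near Kdm4A and on each chromosome arm were compared because the genotypes differ at the Kdm4A locus. Of the 40 measured genes nearest to Kdm4A, 20 on each side by annotation order, 0 were called by limma, with 2 at an unadjusted p under 0.05, against 18 called among 11942 other genes (two-sided Fisher's exact p = 1). Those 2 genes adjoin Kdm4A in the table, 1 on each side: MFS12 differed by -0.44 (SE 0.11, adjusted p = 0.418) and Or43b by -0.38 (SE 0.16, adjusted p = 0.935), both lower in the mutant in 3 of 3 pairs but not called with the block either. The log2 differences of the 40 genes lay between -0.44 and 0.31, and with 10 or 50 genes on each side none was called either. So few genes were called elsewhere that counts of 0 were likely at the same share. They do not show that the neighbours are unaffected. No single arm differed in the share of its genes among the 19 called (two-sided Fisher's exact test, adjusted p from 0.246 to 1). In a test chosen after seeing the data, 2L and 2R were counted as chromosome 2. It held 1 of these 19 genes, Kdm4A itself, against 39.0% of all genes. The odds ratio was 0.0869 (95% interval 0.00209 to 0.551, Fisher's exact p = 0.00156). With 1 array left out, Fisher's exact p ranged from 0.00265 to 0.655. With the replicate block, 4 of 2205 genes on 2L and 6 of 2428 genes on 2R were called, fewer than elsewhere (Fisher's exact adjusted p = 2.57e-04 and 4.42e-04). The called genes included CG15353 on 2L (2.34, SE 0.23 with the block) and Alp7 on 2R (1.09, SE 0.12 with the block). On X 25 of 1873 genes and on 3R 37 of 2974 genes were called, more than on all other arms together (Fisher's exact adjusted p = 0.0203 and 0.0112). Those other arms include 2L and 2R, so the excess on X and 3R is not separate from the shortage there. Fisher's exact test also takes genes as independent, which neighbouring genes may not be. The share was 1.33% on X and 1.24% on 3R, against 1.02% on 3L and 3.08% on chromosome 4. On 3L 24 of 2344 genes were called (Fisher's exact adjusted p = 0.292), and on chromosome 4 it was 2 of 65, Ekar and yellow-h (Fisher's exact adjusted p = 0.14). By camera no arm shifted as a whole (adjusted p from 0.873 to 0.936), but chromosome 4 passed without control replicate 3 (adjusted p = 0.00518).

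**Figure D3:**
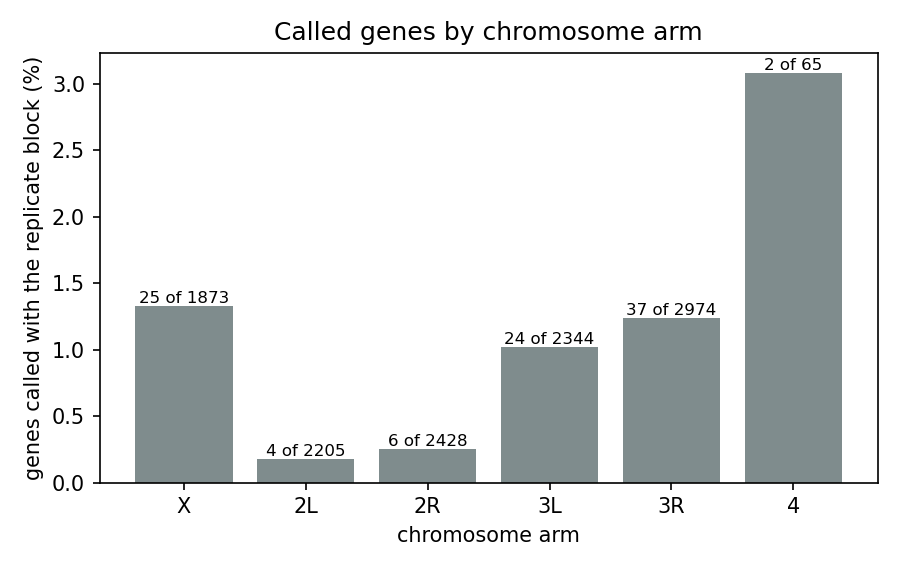
Percent of the measured genes of each chromosome arm (horizontal axis) that were called with the replicate block, with counts above the bars. The share was 0.18% on 2L and 0.25% on 2R, and 1.33% on X, 1.02% on 3L, 1.24% on 3R and 3.08% on chromosome 4.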

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

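The probe sets left out of the gene comparison, which have no gene or several genes in the probe table, also held differences. Of these 5122 probe sets, 8 passed limma at an adjusted p under 0.05 over all probe sets, 5 higher in the mutant than in the control and 3 lower. The differences of the 5 higher probe sets ranged from 0.93 to 1.77 on the log2 scale, and none of them is listed in the probe table. Among the 3 lower ones the largest difference was -1.26.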

How the results depend on the processing

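Of the alternatives, leaving out both arrays numbered 1, leaving out pairs under the block, and the share of called genes on chromosome 2 were chosen after seeing the data. So was the choice to follow 5 single lists, the cuticle list among them, through the alternatives. The count of 19 genes became 11 among the upper 60% of genes, where fewer genes are tested, 35 over all probe sets, where more are tested, 82 with array weights, 98 with the replicate block and 0 without both arrays numbered 1. Leaving out 1 array gave 5 to 18 genes. Those fits had no block and left the groups unequal in array numbers, so their results also reflect differences between the numbers. Under the replicate block, 89 genes were called without pair 1, 110 without pair 2 and 23 without pair 3. Each of these fits leaves 1 residual degree of freedom per gene, so the counts lean on the spread that limma pools over genes. The count of 16 genes changed at least 2-fold became 9, 26, 40, 62 and 0 under the same 5 settings, and 5 to 17 with 1 array left out. For gene lists the count of 3 became 0 with an estimated correlation, 0 with fry, 1 without both arrays numbered 1, and 1 to 3 with 1 array left out. The cuticle list ranged from -0.060, without control replicate 3, to 0.69, without control replicate 1. Its mean was 6.84 in control 3 and 8.35 in control 1, so this range partly reflects the array numbers left unequal. Arms passing Fisher's exact test went from 0 to 1 with the trended robust prior, 3 with array weights and 4 with the replicate block, and arms passing camera were 0 to 1 with 1 array left out. Of called genes, 5.3% lay on chromosome 2 (Fisher's exact p = 0.00156), and 5.6% to 20% with 1 array left out. Fisher's exact p was then 0.655 without mutant replicate 1, mutant replicate 2 or control replicate 2, and 0.096 without mutant replicate 3. It stayed under 0.05 without control replicate 1 (0.0214) or control replicate 3 (0.00265). Kdm4A differed by -2.01 (adjusted p = 0.077) without both arrays numbered 1, and its calls under all other alternatives held, with differences from -1.98 to -1.84; it is below the level kept by the filter, and its 1 probe set leaves no other to test. The 19 genes lost the call in 90 of 278 alternatives. Their direction held in all of these, but leaving out arrays could not have reversed it, because the groups of these genes did not overlap. Over all genes, the block ended the call of the glutathione S-transferase and UDP-glycosyltransferase list. Among the genes named in the report it added the calls of GstD3, Scp1, CG14418, CG10943, CG34330, CG15353, Alp7, yellow-h, ng3 and Mtk. It also added those of CG14417, CG14421, Osi9, CG14960, CG12017 and CG43085. The effect of the block on calls adjusted over a list alone is given there. Apart from the constructions named, the cause was not tested. Dim genes, near the lower end of the log2 values, limit what the arrays can show.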

Other observations

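All tests in this part except the splits of the arrays, the odds ratio for array numbers, the RNA integrity test of the cuticle list and the test of cuticle genes by chromosome were chosen after the results were seen. Cuticle protein genes differed between array numbers. With genotype in the limma fit, arrays numbered 3 had lower cuticle values than arrays numbered 1, by a mean of -1.18 over 106 genes, with 31 called lower and 1 higher (camera adjusted p = 1.70e-18, and adjusted p = 0.772 with an estimated correlation). Cpr65Eb differed by -3.13 (SE 0.22), Cpr66Cb by -2.31 (SE 0.26) and TwdlR by -2.06 (SE 0.22), named after their values were seen. Neuron and glia markers were higher in arrays numbered 3 by a mean of 0.63, with 15 of 24 called (camera adjusted p = 4.75e-08, and adjusted p = 0.772 with an estimated correlation). Chitin and peritrophic matrix genes were lower by a mean of -0.42, with 12 of 40 called (camera adjusted p = 1.35e-04, and adjusted p = 0.772 with an estimated correlation). Muscle sarcomere genes were higher by a mean of 0.27, with 0 of 26 called (camera adjusted p = 0.0326, and 0.772 with an estimated correlation). At the preset correlation the lists of DNA replication (-0.21), antimicrobial peptides (-0.42) and Polycomb and Trithorax genes (0.18) passed too (camera adjusted p = 0.00296, 0.0128 and 0.0468). The ecdysone list did not pass (camera adjusted p = 0.585), with 4 of 31 members called lower and 2 higher. Among those lower were ImpE1 (-2.44, SE 0.21), ImpE2 (-2.93, SE 0.27) and ImpL1 (-2.56, SE 0.29), named after their values were seen.

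With genotype in the fit the arrays thus differed by number, with 989 genes called between numbers 3 and 1, 59 between numbers 3 and 2 and 0 between numbers 2 and 1 (limma, 2 arrays per number). At an unadjusted p under 0.05 there were 3159, 2008 and 1396 genes in the same order. The 3′ to 5′ gaps were similar in numbers 2 and 3 while number 1 stood apart. With 0 genes called between numbers 2 and 1, the 59 genes cannot be set against a share of that count. By the unadjusted counts numbers 3 and 2 differed at more genes than numbers 2 and 1, which a difference in gap alone would not give. RNA integrity stays open as a part of the difference. No biological explanation was tested, because the labels give no property of the numbers.

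Few of the called genes lay on chromosome 2. With the replicate block 10 of 98 called genes were on it, against 39.0% of all genes (odds ratio 0.176, 95% interval 0.0816 to 0.34, Fisher's exact p = 2.25e-10), and without the block Kdm4A was the 1 of 19. A candidate explanation is that the stocks differ in the genetic background of the chromosomes other than chromosome 2, with variants acting on nearby genes, and the odds ratio of 0.176 goes with it but was found in the same data. Gene content of chromosome 2 stays open in part, since the 189 placed genes called over all 3 array numbers at once were also fewer there (odds ratio 0.623, 95% interval 0.444 to 0.862), though less so. Effects of Kdm4A on genes elsewhere remain open too, since background differences would follow the genotypes exactly and the labels do not describe them. Fisher's exact test takes genes as independent in each of these counts. The genes called with the block on X included CG14417, CG14418, CG14419 and CG14421, all lower in the mutant and named after their values were seen. If genes with such close CG numbers vary together, the intervals are too narrow and the p values too small.

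The higher mean of the cuticle list in the mutant, 0.27 with a standard error of 0.23 between the 3 pairs, has several open explanations. The group difference in 3′ to 5′ gap predicted a shift of -0.10 (standard error 0.12), of the other sign, which meets the bound set beforehand against RNA integrity, but only by 0.23 with a standard error of 0.21 between pairs, and not in pair 1, so RNA integrity is not excluded. Background variants on other chromosomes are not excluded either: the 30 cuticle genes on chromosome 2 had a mean of 0.20 (95% bootstrap interval over genes 0.01 to 0.41), against 0.30 for the 76 others. The bound of 0 set beforehand was too loose because the interval holds 0.07, the highest value that this explanation allows. The bootstrap drew genes, which are not independent, and not larval pools, so its interval leaves out the spread between the 3 pairs. A difference in developmental timing between pools stays open, as no test here decides it: across 11983 genes, which are not independent replicates, the mutant difference correlated with the difference between numbers 3 and 1 at 0.191 (0.083 over the cuticle genes), but cuticle values were lower in arrays numbered 3, so this would predict a lower list in the mutant. A role of Kdm4A itself stays open and untested.

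Other splits of the 6 arrays into 3 and 3 show how far the counts rest on the grouping, though 10 splits are too few for a share under 0.05. The genotypes gave 19 genes, and the highest other split gave 44, so 2 of the 10 splits called as many. That split set mutant 1, mutant 2 and control 1 against the rest, while the split of mutant 1, control 1 and control 2 against the rest, which also parts numbers 1 and 3, called 0 with limma, with 1337 genes at an unadjusted p under 0.05. For genes changed at least 2-fold the values were 16 and 41, again 2 of 10. Over gene lists the genotypes gave 3 and the highest other split 7, and 9 of the 10 splits called at least 3. With the block, among the 4 splits that part all pairs, the genotypes gave 98 genes and the highest other 0, so 1 of 4 reached that count. At an unadjusted p under 0.05 these splits gave 1339 genes for the genotypes and at most 351 for the others. Each of the others swaps 1 pair, so a steady difference between the genotypes adds to their residual spread and lowers their counts. Their counts lie below the 599 that chance gives. They are thus no measure of chance for the 98 or the 1339 genes.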
